A study of Drosophila melanogaster with 10 samples.

How the data were processed

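The series holds RNA sequencing of whole third-instar *Drosophila melanogaster* larvae of 5 genotypes, with 2 libraries each. Per the labels, the strain background is y1w1118, larvae were kept at 25 °C, RNA came from 100 mg of larvae, 50 ng of total RNA went into oligo(dT) selection, and libraries were made with the NEBNext Ultra kit, 12 PCR cycles and paired reads on an Illumina NovaSeq. The genotypes are wild type, dCTCFΔCP (called the CTCF mutant here), dCTCFΔCP with Su(Hw)Δ114 (the CTCF Su(Hw) mutant), dCTCFΔCP with PitaΔCP1 (the CTCF Pita mutant), and all of these together (the triple mutant). There is no Su(Hw) or Pita mutant with intact CTCF, so the effect of either mutation was measured on the CTCF mutant background. The labels name no batch, date, sex or pairing between libraries. Whether the libraries of the CTCF Su(Hw) mutant, which differ by little more than counting error, come from separate RNA samples is not given in the sources used here. If they do not, n = 2 is 1 biological sample there, and p-values that use this group are too small. Those of the other comparisons would then be too small as well, since the spread was estimated over all 5 groups together.

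The authors deposited 1 table per library of raw counts per gene, in the layout of the gene count output of STAR, with 3 count columns for the strand settings and 4 summary lines. Per the labels, reads were trimmed with cutadapt and aligned with STAR to dm6; versions, the annotation release, read filters and whether a count is a read or a read pair are not given in the sources used here. Counts are called reads below. The unstranded column was used, since reads fell on the forward strand in 50.1% to 50.3% of stranded assignments. Reads from overlapping or antisense genes can therefore not be told apart by strand, and near-identical copies such as the Hsp70 genes or PGRP-SC1a and PGRP-SC1b are uncertain because reads that map to several places were not counted. Of 17735 gene identifiers in the files, 17597 (99.2%) have a name in the annotation used here, and the other 138 were kept under their identifier.

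Groups were taken from the labels. The comparisons, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. Each of the 4 mutant genotypes was compared with wild type. The CTCF Su(Hw) and the CTCF Pita mutant were each compared with the CTCF mutant, and the triple mutant with each of these. The last of the 9 comparisons was the interaction of the Su(Hw) and Pita mutations on the CTCF background, which asks whether the effect of both together differs from the sum of their separate effects on the log2 scale. Genes with enough reads were kept with filterByExpr of edgeR at its defaults, which left 10585 genes and removed 7150. At least 99.66% of the assigned reads of every library stayed. Counts were scaled with TMM factors, which ran from 0.553 to 1.35, and tested with the quasi-likelihood F-test of edgeR 4.0.16 in 1 model of all 10 libraries, with R 4.3.3. The p-values were adjusted within each comparison with the Benjamini-Hochberg method and called at 0.05. Tests are two-sided. An exact permutation test of 2 libraries against 2 could not go below p = 0.333, so all gene tests rest on the variance model, which had 5 residual degrees of freedom, a median prior of 6.22 and a biological coefficient of variation of 15.9%. The p-values measure the spread between libraries of a group, which may be technical.

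Levels are given as CPM, reads scaled to a common size of the TMM-adjusted library, as mean ± SD over the n = 2 libraries of a group, and differences as the log2 fold change with its standard error (SE). A single read stands for 0.0927 to 0.289 CPM, and 0 reads in a library allow up to 3 reads, which is 0.278 to 0.868 CPM. Where a group had 0 reads, the fold is given as a lower bound with 3 reads in place of 0. Where it had 1 to 3 reads, the ratio of scaled reads is given with its 95% exact interval, since the fitted fold then depends on the prior count. Intervals, bounds and floors cover counting error alone, and PCR copies are not independent molecules.

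Genes were named by rule. In each comparison with wild type these are the 8 genes with the largest rise and the 8 with the largest fall among those called, with libraries of the groups not overlapping, at least 5 CPM in the higher group and a name other than a placeholder, plus 3 in each direction whatever the name. For the steps between mutants 5 in each direction were taken, and for the interaction the 5 with the smallest adjusted p. CTCF, su(Hw), pita, Cp190, y, w and the 8 Hox genes were always looked at. For each gene list up to 4 called members with the largest change could be named. Of these sets the text names those that were least moved by single libraries, and others where they were needed to describe a group.

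In all, 33 gene lists were fixed from textbook knowledge: insulator and architectural proteins, Hox genes, patterning genes, neuronal genes, neuropeptides, glial genes, testis genes, Y-linked genes, germline genes, dosage compensation, fat body genes, lipid metabolism, salivary glue genes, late ecdysone-response genes, early ecdysone-response genes, ecdysone synthesis, cuticle genes, Osiris genes, digestive enzymes, antimicrobial genes, heat shock genes, Turandot genes, cytochrome P450 genes, glutathione S-transferases, UDP-glycosyltransferases, muscle genes, hemocyte genes, proliferation genes, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, nuclear oxidative phosphorylation genes, mitochondrially encoded genes and histones. Lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Member counts are given after adjustment over all genes, and again adjusted over the list alone. A separate camera run estimated the correlation from the data. None of the 119 list calls (out of 279 tests) was kept there, where 24 tests had an unadjusted p under 0.05. The alternative fry, which asks whether the genes of a list move one way, called 102. It lost 40 of the 119 calls and made 23 others.

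Overlaps between comparisons were set against the number that independent draws would give, which does not allow for a shared control. Where a control was shared, the covariance of the log2 fold changes over all genes was set against its mean in 20 simulations with that control and no gene changed. Genes near the 3 mutated loci (within 1 Mb) were compared with the rest by Fisher's exact test. The pipeline was tested on simulated data: reads of all 10 libraries were drawn, with known changes added to few genes of 1 group. For the CTCF mutant against wild type, 86.2% of 4-fold, 48.4% of 2-fold and 6.06% of 1.5-fold changes were recovered, with 2 false calls among 93. Recovery was lowest for the interaction. False calls reached 12 among 93 for the CTCF Su(Hw) against the CTCF mutant, more than the cutoff allows. Where nothing differed, 0 or 1 gene was called. Alternatives planned in advance were RLE and upper-quartile factors, no filter or a filter at 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, a model of only the groups compared, replicate number as a block, a change of at least 2-fold, each library left out in turn, and, for the loci, windows of 0.5 and 2 Mb. Those added after the data were seen were summing the libraries of the CTCF Su(Hw) mutant, leaving out wild type 1, CTCF Pita 1 and triple 2 together, which were chosen after the levels of the gene lists were seen, removing mitochondrially encoded genes, and the mean level of the glue genes as a covariate. That choice is not a rule: with 2 libraries per group neither is defined as the 1 that departs, and the CTCF libraries, with the most genes over 2-fold apart (918), are not among the 3. No library was left out of the values reported first. Genes below the filter were not tested.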

Results

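Whole third-instar larvae of 5 genotypes were sequenced, 2 libraries each, to ask how gene expression depends on the parts of the architectural zinc-finger proteins CTCF, Su(Hw) and Pita that contact CP190, a protein that such DNA-binding proteins bring to insulators and promoters. Each library held 18856997 to 24391317 reads. Reads assigned to genes numbered 6901253 and 6537264 in wild type, 6253318 and 5670793 in the CTCF mutant, 8220126 and 8057426 in the CTCF Su(Hw) mutant, 6417192 and 7684882 in the CTCF Pita mutant, and 7966813 and 5693588 in the triple mutant. That is 25.6% to 39.8% of all reads, since 50.9% to 65.5% mapped to several places. Between 11801 and 13567 genes had at least 1 read. Transcripts encoded by mitochondrial DNA took 34.6% and 24.2% of the assigned reads in the CTCF mutant, against 14.2% and 14.6% in wild type, 8.67% and 8.80% in the CTCF Su(Hw) mutant, 18.7% and 12.9% in the CTCF Pita mutant and 11.7% and 18.1% in the triple mutant. Libraries are named by group and replicate, such as wild type 1.

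The first principal component (45% of the variance of log2 CPM) placed wild type (-44.2 and -29.1) and the CTCF mutant (-65.8 and -56.6) apart from the 3 genotypes with a Su(Hw) or Pita mutation (9.57 to 45.6). The second (18.1%) set the triple mutant (-31.3 and -60.6) apart from the rest. Replicates differed in closeness. Of the 10585 genes tested, 93 lay more than 2-fold apart in CPM between the libraries of the CTCF Su(Hw) mutant, against 360 to 918 in the other groups. Among the 10324 genes with at least 20 reads in these libraries together, the spread was close to counting error. Its chi-square per degree of freedom was 1.785, against 14.35 to 41.41 in the other groups. Wild type 1 and 2 differed most in 2 developmentally timed groups: the salivary glue genes had a mean level of 5.63 and 2.88 log2 CPM, and the Osiris genes, expressed in cuticle-forming epithelia, 3.82 and 0.93. CTCF Pita 1 lay above CTCF Pita 2 in heat shock genes (4.13 against 2.94 log2 CPM) and in late and early ecdysone-response genes (5.09 against 2.97 and 5.21 against 4.59), and triple 2 lay above triple 1 in mitochondrially encoded genes (10.6 against 9.25). With 2 libraries per group, which of them departs from its group is not defined.

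**Figure D1:**
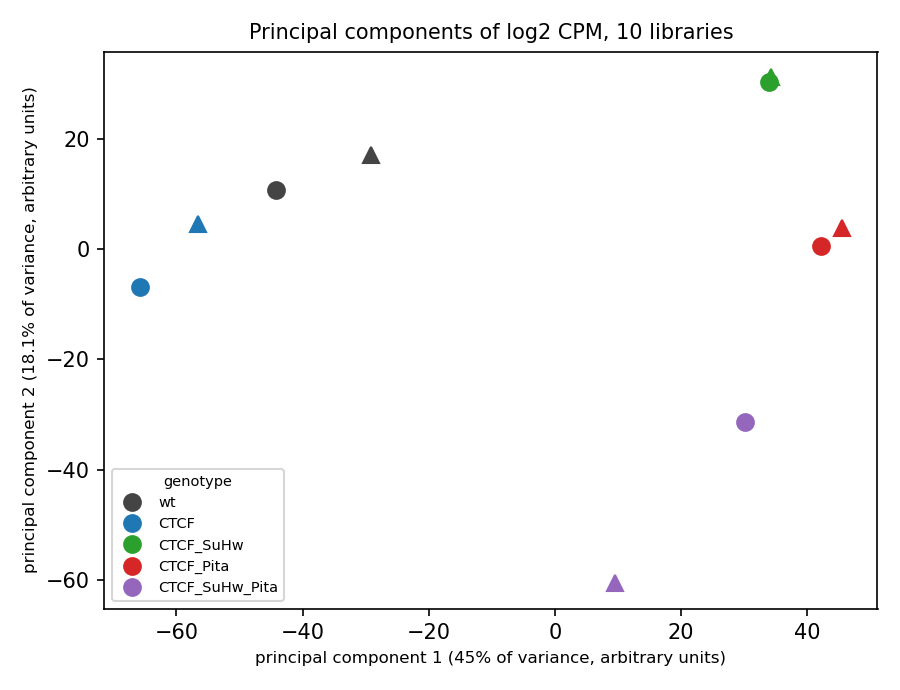
First and second principal components of log2 CPM over 10585 genes, 1 point per library, with the share of variance on each axis. Wild type and the CTCF mutant lie below 0 on the first component and the other genotypes above 0, with the libraries of the CTCF Su(Hw) mutant almost on top of each other.

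The mutated genes were read first as a check of the labels. The su(Hw) gene (FBgn0003567; dm6 3R, 14304455 to 14308589) stood at 25.7 ± 0.82 CPM in wild type (mean ± SD, n = 2), 21.2 ± 0.69 in the CTCF mutant and 23.8 ± 0.631 in the CTCF Pita mutant, but at 488 ± 11.7 in the CTCF Su(Hw) mutant and 479 ± 131 in the triple mutant. The pita gene (FBgn0034878; 2R, 23548967 to 23554712) stood at 27.8 ± 5.24 CPM in wild type, 23.2 ± 8.13 in the CTCF mutant and 18.8 ± 2.37 in the CTCF Su(Hw) mutant, and at 160 ± 11.6 and 192 ± 36.1 in the CTCF Pita and triple mutants. Against wild type, su(Hw) rose in both genotypes that carry its mutation (log2 fold change 4.25, SE 0.22, adjusted p = 7.23e-07, and 4.22, SE 0.22, adjusted p = 1.08e-06), as did pita (2.52, SE 0.24, adjusted p = 6.4e-05, and 2.79, SE 0.24, adjusted p = 2.37e-05). Dcp-1 lies on the opposite strand inside the span of pita (2R, 23551313 to 23553547), and unstranded counts do not separate them fully. The w gene (FBgn0003996; X, 2790599 to 2796466), which is needed for eye pigment, is mutated in this strain background and is a common transgene marker, stood at 0.953 ± 0.424 CPM in wild type, 0.271 ± 0.0259 in the CTCF mutant, 28.9 ± 0.401 in the CTCF Su(Hw) mutant, 2.97 ± 1.06 in the CTCF Pita mutant and 19.7 ± 0.221 in the triple mutant. CTCF itself (FBgn0035769; 3L, 7353578 to 7356713) was at 14.2 ± 0.372 CPM in wild type, 6.83 ± 1.8 in the CTCF mutant, 11.1 ± 0.0788 in the CTCF Su(Hw) mutant, 21.0 ± 0.115 in the CTCF Pita mutant and 22.3 ± 5.98 in the triple mutant. Cp190 (FBgn0000283) passed no test against wild type (44.8 ± 1.95 CPM). It rose from 24.9 ± 1.61 CPM in the CTCF mutant with an added Su(Hw) (49.85 ± 1.01, adjusted p = 0.0466) or Pita mutation (52.5 ± 4.13, 0.0336).

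**Figure D2:**
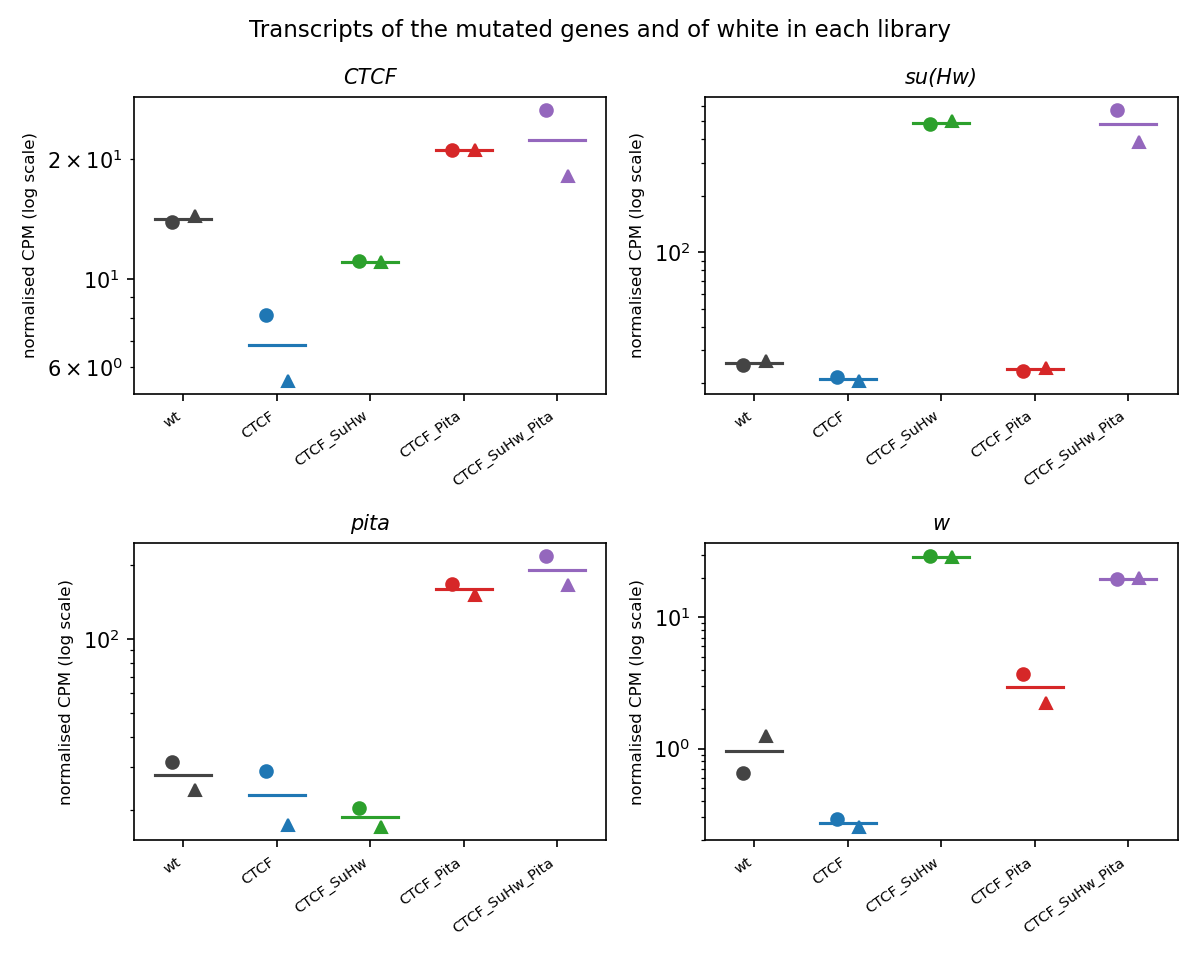
Level of CTCF, su(Hw), pita and w in each library in CPM on a log axis, with circles for replicate 1, triangles for replicate 2 and a bar at the group mean. Mean su(Hw) is 488 and 479 CPM and mean pita 160 and 192 CPM in the genotypes with their mutations.

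The CTCF mutant against wild type asks what follows when the CP190-contacting part of CTCF alone is changed. The gene for the C-type lectin lectin-28C (FBgn0040099; 2L, 7857077 to 7860120) fell from 103 ± 9.94 to 2.46 ± 0.616 CPM (n = 2 each; log2 fold change -5.39, SE 0.26, adjusted p = 2.58e-06). CG31219 (FBgn0051219; 3R, 19651018 to 19652430) had 124 reads in wild type and 0 in the mutant, at least 24.5-fold lower (adjusted p = 0.00236). Tsp42Ep, a tetraspanin gene, rose from 1.05 ± 0.37 to 30.0 ± 1.52 CPM (4.83, SE 0.35, adjusted p = 5.52e-05). Also higher were PGRP-SC1a, a peptidoglycan-degrading amidase gene (44.3 ± 13 against 2.09 ± 0.741 CPM, log2 fold change 4.40), ss (FBgn0003513; 3R, 16374434 to 16403690), which encodes the transcription factor spineless that sets antennal and leg identity (17.7 ± 1.36 against 1.68 ± 0.163 CPM, 3.39), and Cyp6g1, a detoxifying P450 gene (188 ± 12.7 against 20.9 ± 4.35 CPM, 3.16). Iris, a gene derived from a viral envelope gene, fell by 2.53 on the log2 scale. In all, 357 of 10585 genes were called by edgeR, 233 higher and 124 lower, with 2019 at an unadjusted p under 0.05, and 53 were called with the glue score as a covariate. The larger side turned under library totals (97 higher and 1217 lower), without wild type 2 (42 and 57) and with the glue score (21 and 32). The count rested on single libraries, where the library left in a group is assumed to vary like the other groups: it was 190 without wild type 1, 99 without wild type 2, 67 without CTCF 1, 132 without CTCF 2, 143 and 142 without CTCF Su(Hw) 1 and 2, and 819 and 835 without triple 1 and 2.

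Among the gene groups, mitochondrially encoded genes were higher in the CTCF mutant, with 13 of 14 called (14 adjusted over the list alone), a median log2 fold change of 2.05 and a camera adjusted p = 6.13e-12, beside the raised share of mitochondrial reads given above. Nuclear oxidative phosphorylation genes were tested as higher, but with a median below 0 under scaling by library totals (median 0.54, adjusted p = 1.12e-11; 3 of 77 called, 40 adjusted over the list alone). The same, with the same turn under library totals, was seen for cytosolic ribosomal proteins (median 0.39, adjusted p = 6.99e-11; 1 of 89 called, 0 adjusted over the list alone) and mitochondrial ribosomal proteins (0.32, adjusted p = 3.37e-08; 1 of 70, and 1 adjusted over the list alone). Library totals as scaling moved the median of all genes by -0.58 in this comparison. Digestive enzymes, such as the trypsins and Jonah proteases of the gut, were higher (median 0.88, adjusted p = 3.37e-08), with 6 of 47 called higher and 1 lower (15 and 1 adjusted over the list alone). Salivary glue genes, which larvae express before pupariation, were higher as a list (median 2.08, adjusted p = 0.000139; 1 of 11 called, 6 adjusted over the list alone), with wild type 1 and 2 far apart in them as given above. Glutathione S-transferases, which conjugate toxic compounds, were higher too (0.35, adjusted p = 0.00197; 4 of 31 called, 5 adjusted over the list alone), but below 0 under library totals. Hemocyte genes were lower (median -0.38, adjusted p = 0.00435; 2 of 17 called, 4 adjusted over the list alone). None of the 16 list calls in this comparison was kept with an estimated correlation (adjusted p = 0.531 to 0.63).

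The fat body list, with storage and lipid-carrier proteins, was higher (median 0.36, adjusted p = 0.0147, adjusted p = 0.531 with an estimated correlation; 2 of 13 called higher and 1 lower, 4 and 1 adjusted over the list alone), though below 0 under library totals and not called without CTCF 1 (adjusted p = 0.057). Its called members included Lsp1alpha, a larval serum protein gene (10920 ± 181 against 2908 ± 452 CPM, log2 fold change 1.91, adjusted p = 0.00303). The other 7 called lists (adjusted p = 0.0059 to 0.0395, and 0.531 to 0.63 with an estimated correlation) each lost the call without at least 1 library. Cuticle, P450 and UDP-glycosyltransferase genes (higher, but lower under library totals) lost it without wild type 2 (adjusted p = 0.645, 0.196 and 0.149). Cuticle genes also lost it without CTCF 2 (0.291) and P450 genes without CTCF 1 (0.0608). Heat shock genes (higher) lost it without wild type 1 or 2 (0.136 and 0.0814), CTCF 1 (0.153) and triple 1 or 2 (0.075 and 0.0727). Testis genes (lower) lost it without wild type 2 (0.727) and CTCF 1 (0.19), Osiris genes (lower) without wild type 1 (0.136), and neuropeptides (lower) without wild type 2 (0.149), CTCF 2 (0.291) and triple 1 or 2 (0.0548 and 0.0603). CTCF mRNA was called lower (log2 fold change -1.06, adjusted p = 0.0464), a call lost without wild type 1 or 2 (0.116 and 0.214), CTCF 1 or 2 (0.134 and 0.231), CTCF Su(Hw) 1 or 2 (0.0979 and 0.0965) and CTCF Pita 1 or 2 (0.0601 and 0.0611).

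**Figure D3:**
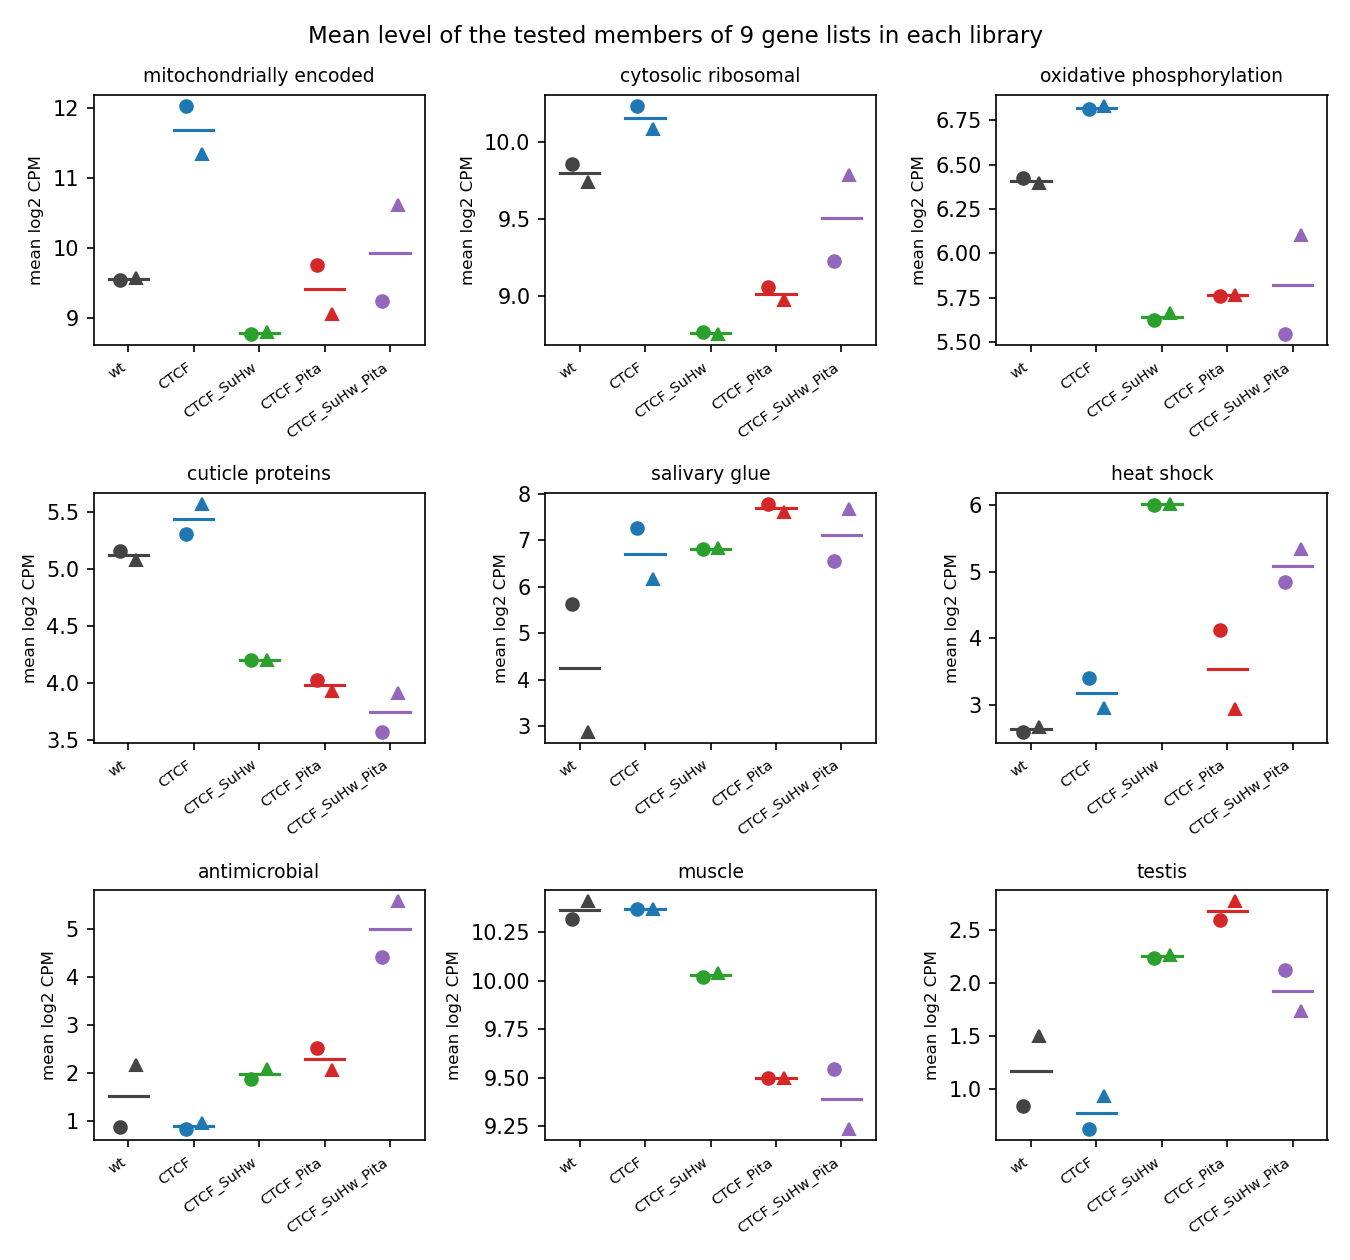
Mean log2 CPM of the tested members of 9 gene lists in each library, by genotype. Mitochondrially encoded genes reach 12.0 and 11.3 in the CTCF mutant against 9.55 and 9.57 in wild type, and antimicrobial genes reach 4.41 and 5.57 in the triple mutant.

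The CTCF Su(Hw) mutant against wild type asks what both mutations do together. Heat shock genes rose: Hsp70Bb, 1 of several near-identical chaperone genes, had 1070 reads against 0 in wild type, at least 210-fold higher (50.5 ± 10.9 CPM, n = 2; adjusted p = 1.77e-05). Mal-A7 and Mal-A8, maltase genes of the gut, rose to 26.3 ± 0.737 from 0.398 ± 0.101 CPM and to 68.8 ± 6.44 from 3.06 ± 1.45 CPM (log2 fold change 5.98, SE 0.40, and 4.49, SE 0.36). Fbp1, the fat body receptor for storage proteins that ecdysone switches on, rose to 2636 ± 45.8 from 96.6 ± 29.4 CPM (4.77, SE 0.47, adjusted p = 6.49e-05), w by 4.89 (SE 0.29, adjusted p = 2.33e-06) and the P450 gene Cyp4e3 by 4.51 (SE 0.21, adjusted p = 4.88e-07). MtnB, a metallothionein gene, fell from 26.4 ± 2.48 to 1.13 ± 0.374 CPM (-4.52, SE 0.33, adjusted p = 8.73e-06). A pair of neighbouring genes on the X fell to almost no reads: CG14419 (FBgn0029639; X, 2885186 to 2885914) had 0 reads against 379, at least 214-fold lower, and CG3588 (FBgn0025643; X, 2919770 to 2924426) had 1 against 2672, a ratio of 4540 (95% interval 813 to 179000). The fitted log2 fold change of CG3588 was -11.70 and went to -10.88 and -13.56 without CTCF Su(Hw) 1 or 2. CG32845, with 274 reads against 0, was at least 53.8-fold higher. The test called 3520 of 10585 genes, 1673 higher and 1847 lower, a split whose larger side turned in 3 of 23 alternatives, such as RLE factors (1815 and 1719), and under library totals (3128 and 509). The count was 1497 without wild type 1, 1381 and 1142 without CTCF Su(Hw) 1 and 2, and 1382 with these libraries summed. It was 2232 with the glue score as a covariate.

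In the same comparison heat shock genes were called in 14 of 15 tested (14 adjusted over the list alone; median log2 fold change 2.97, adjusted p = 1.41e-10). Neuronal genes were higher in 15 of 30 (16 adjusted over the list alone; median 0.66, adjusted p = 7.72e-06), among them brp, which encodes the active zone protein Bruchpilot (95.6 ± 7.19 against 7.20 ± 0.213 CPM, log2 fold change 3.73, adjusted p = 2.16e-06), and cac, a synaptic calcium channel gene (1.57, adjusted p = 0.00409). Testis genes were higher in 21 of 34 and lower in 1 (the same adjusted over the list alone; median 1.46, adjusted p = 6.57e-06). Cytosolic ribosomal protein genes were lower in 81 of 89 and higher in 1 (82 and 1 adjusted over the list alone; median -1.11, adjusted p = 5.37e-23), for example RpL36 (519 ± 0.336 against 1764 ± 221 CPM, -1.77), RpL9 (-1.57) and RpL23 (-1.54). Mitochondrial ribosomal proteins were lower in 42 of 70 (49 adjusted over the list alone; -0.67, adjusted p = 4.11e-12), as with mRpL4 (-1.43) and mRpL9 (-1.29). Nuclear oxidative phosphorylation genes were lower in 60 of 77 and higher in 2 (62 and 4 adjusted over the list alone; -1.04, adjusted p = 2.62e-13), for example ND-B14.5A of complex I (-1.89, adjusted p = 0.000631). Cuticle genes were lower in 37 of 64 and higher in 1 (38 and 3 adjusted over the list alone; -1.17, adjusted p = 6.95e-09), among them the adult cuticle gene Acp65Aa (-2.87, adjusted p = 0.00263). Osiris genes were lower in 6 of 7 (6 adjusted over the list alone; -5.77, adjusted p = 0.00288), in which wild type 1 stood far above wild type 2 (3.82 and 0.93 log2 CPM). Osi2 had 0 reads against 42, at least 23.8-fold lower. None of these lists was called with an estimated correlation (adjusted p = 0.39 to 0.621).

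Muscle genes were lower in 9 of 24 and higher in 1 (10 and 1 adjusted over the list alone; median -0.36, adjusted p = 0.00517, adjusted p = 0.39 with an estimated correlation), with a median above 0 (0.12) under library totals. The troponin C genes TpnC25D (43.8 ± 3.32 against 150 ± 13.7 CPM, log2 fold change -1.78) and TpnC47D (-1.40) were among them. Mitochondrially encoded genes were called lower (median -0.78, adjusted p = 0.0375, adjusted p = 0.853 with an estimated correlation; 2 of 14 called, 0 adjusted over the list alone), a call lost without wild type 2 (adjusted p = 0.0717) and CTCF Su(Hw) 1 (0.0535), beside the lower mitochondrial share of reads given above. Called members of lists that were not called included NimC1, a phagocytosis receptor gene of hemocytes (6.45 ± 0.718 against 22.6 ± 0.347 CPM, -1.81), Kr, a segmentation gene (-1.08), and the gut peptide genes AstA (-1.38) and CCHa2 (-1.36), all lower. The lipid oxidation gene whd, which encodes carnitine palmitoyltransferase, was higher (0.87, adjusted p = 0.00325). The level of pita was 0.56 lower on the log2 scale without passing the test (adjusted p = 0.0896). Library totals as scaling moved the median of all genes by 0.48 here.

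The CTCF Pita mutant against wild type asks the same for Pita. PGRP-SC1a rose from 2.09 ± 0.741 to 361 ± 51.8 CPM (n = 2; log2 fold change 7.43, SE 0.34, adjusted p = 7.19e-07). Cralbp, a retinoid-binding protein gene, had 118 reads against 2, a ratio of 40.0 (95% interval 10.8 to 334). The most lowered genes included Mdr50, a drug transporter gene (3.09 ± 0.681 against 39.8 ± 14.4 CPM, -3.66), Btnd (4.17 ± 0.642 against 47.3 ± 1.97 CPM, -3.49), krimp, a gene of the piRNA pathway of the germline (1.03 ± 0.0486 against 9.06 ± 1.29 CPM, -3.12), and the cuticle genes Lcp65Ae (-3.32) and Cpr78Cc (16.7 ± 0.42 against 132 ± 6.85 CPM, -2.98, adjusted p = 1.99e-06). CG11300 fell from 172 ± 44.9 to 11.5 ± 1.19 CPM (-3.90, SE 0.25, adjusted p = 8.57e-06). The genes for the prophenoloxidases of crystal cells, PPO1 and PPO2, fell by 1.94 and 1.97, and ACC and FASN1, of fatty acid synthesis, by 1.64 and 1.61. The lipid metabolism list that holds ACC and FASN1 was not called (adjusted p = 0.21; 3 of 15 higher and 7 lower). Here w was called as higher (log2 fold change 1.58, adjusted p = 0.00843), and not without wild type 1 (adjusted p = 0.0834) or CTCF Pita 1 (0.0578). The test called 4001 genes, 1970 higher and 2031 lower, a split whose larger side turned in 4 of 23 alternatives, such as RLE factors (2112 and 1850), and under library totals (3408 and 571). The count was 1956 without wild type 1 and 1645 with the glue score as a covariate.

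Neuronal genes were higher in the CTCF Pita mutant in 18 of 30 (21 adjusted over the list alone; median log2 fold change 0.97, adjusted p = 6.76e-07), such as fne, an RNA-binding protein gene (23.4 ± 4.22 against 5.89 ± 1.86 CPM, 1.98), and Rdl, a GABA receptor gene (1.64). Testis genes were higher in 22 of 34 (23 adjusted over the list alone; 1.90, adjusted p = 1.6e-08), as with the sperm protein gene Mst84Dd (7.81 ± 0.000728 against 1.04 ± 0.0823 CPM, 2.89). Muscle genes were lower in 19 of 24 (20 adjusted over the list alone; -0.96, adjusted p = 4.17e-08), for example TpnC25D (-1.69), TpnC47D (-1.40) and Mp20 (1049 ± 51.5 against 2570 ± 42.0 CPM, -1.29). Cuticle genes were lower in 43 of 64 and higher in 3 (46 and 3 adjusted over the list alone; -1.37, adjusted p = 2.64e-11). Cytosolic ribosomal proteins were lower in 73 of 89 and higher in 1 (80 and 1 adjusted over the list alone; -0.83, adjusted p = 1.8e-15), with RpL24 (-1.36) and RpL41 (-1.33) as examples. Mitochondrial ribosomal proteins were lower in 52 of 70 (56 adjusted over the list alone; -0.76, adjusted p = 5.17e-13). Nuclear oxidative phosphorylation genes were lower in 62 of 77 and higher in 8 (62 and 10 adjusted over the list alone; -1.09, adjusted p = 2.9e-11). The raised members included COX7CL, a paralog of a cytochrome c oxidase subunit known from the testis (2.48 ± 0.175 against 0.320 ± 0.00949 CPM, 2.89), a call lost with the glue score as a covariate. The lists named so far had adjusted p = 0.117 to 0.563 with an estimated correlation.

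Glutathione S-transferases were lower in 17 of 31 and higher in 1 (17 and 2 adjusted over the list alone; median log2 fold change -0.67, adjusted p = 0.000288, adjusted p = 0.386 with an estimated correlation), among them GstD7 (6.85 ± 0.137 against 27.7 ± 0.594 CPM, -2.01) and GstE9 (-1.73). Hemocyte genes were lower in 9 of 17 (9 adjusted over the list alone; -0.78, adjusted p = 0.00357, adjusted p = 0.191 with an estimated correlation). Early ecdysone-response genes, which the molting hormone switches on, were higher in 9 of 17 and lower in 2 (the same adjusted over the list alone; 0.78, adjusted p = 0.00658, adjusted p = 0.43 with an estimated correlation). Of these Eip93F rose by 4.89 on the log2 scale, but by 2.94 without CTCF Pita 1, the library with the higher level of ecdysone-response genes, and by 5.70 without CTCF Pita 2. Heat shock genes were higher in 6 of 15 (7 adjusted over the list alone; 1.40, adjusted p = 0.0301, adjusted p = 0.6 with an estimated correlation), a call lost without wild type 1 (adjusted p = 0.0526) and CTCF Pita 1 (0.44), the library with the higher heat shock level. P450 genes were lower in 22 of 71 and higher in 5 (the same adjusted over the list alone; -0.34, adjusted p = 0.0317, adjusted p = 0.563 with an estimated correlation), with a median above 0 (0.14) under library totals, which move the median of all genes by 0.49. That call was lost without wild type 1 (adjusted p = 0.105) and CTCF Pita 1 (0.131). Cyp9b1 (-1.88) and Cyp4p2 (-1.72) were among the lowered P450 genes. CTCF mRNA was called higher (0.57, adjusted p = 0.0435), and not called without wild type 1 or 2 (0.185 and 0.146), CTCF 1 or 2 (0.0551 and 0.0544), CTCF Su(Hw) 1 or 2 (0.0823 and 0.0813) or CTCF Pita 1 or 2 (0.104 and 0.123).

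The triple mutant against wild type asks what follows when all 3 proteins are changed. Lip3, a lipase gene of the gut (FBgn0023495; 3R, 13370240 to 13371904), rose from 1.03 ± 0.761 to 342 ± 33.8 CPM (n = 2; log2 fold change 8.34, SE 0.37, adjusted p = 3.52e-07; 7.76 and 9.37 without wild type 1 or 2). PGRP-SC1a rose from 2.09 ± 0.741 to 279 ± 54.3 CPM (7.05, SE 0.33), and Dso1, an immune-induced peptide gene, from 1.03 ± 0.987 to 99.1 ± 24.1 CPM (6.56, SE 0.51; 5.84 and 8.15 without wild type 1 or 2). The protease gene CtsL3 had 269 reads against 0, at least 78.3-fold higher (a call lost with the glue score as a covariate), and Hsp70Bb 167 against 0, at least 48.6-fold. The maltase genes Mal-A1 and Mal-A6 rose by 3.86 and 3.38, Fbp1 by 4.06, w by 4.34 and Cyp4e3 by 3.41. CG3588, with 0 reads against 2672, was at least 1020-fold lower and CG14419, with 0 against 379, at least 145-fold. Ccp84Aa, a cuticle protein gene, fell from 9.83 ± 0.727 to 0.415 ± 0.0185 CPM (-4.50, SE 0.37, adjusted p = 1.63e-05). Of single lipid genes, FASN1 and ACC of fatty acid synthesis fell by 2.28 and 2.11, and AcCoAS, which makes acetyl-CoA, by 1.87, but the lipid metabolism list was not called (adjusted p = 0.508; 4 of 15 higher and 4 lower). In all, 2248 genes were called, 1157 higher and 1091 lower (1081 and 1206 with upper-quartile factors; the larger side turned in 12 of 23 alternatives). The count was 1305 and 1364 without wild type 1 or 2, and 873 with the glue score as a covariate.

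In the triple mutant antimicrobial genes were higher in 29 of 35 (32 higher and 1 lower adjusted over the list alone; median log2 fold change 4.06, adjusted p = 5.44e-14), and heat shock genes in 12 of 15 (14 adjusted over the list alone; 2.53, adjusted p = 3.94e-09). Digestive enzymes were higher in 23 of 47 and lower in 4 (28 and 6 adjusted over the list alone; 1.15, adjusted p = 2.81e-06). Testis genes were higher in 6 of 34 (9 adjusted over the list alone; 0.81, adjusted p = 0.000201), such as Mst84Db (6.74 ± 2.43 against 1.83 ± 0.511 CPM, 1.92) and fzo, the gene for a mitofusin of spermatids (1.45). Muscle genes were lower in 21 of 24 (21 lower and 1 higher adjusted over the list alone; -1.02, adjusted p = 3.17e-11), for example TpnC47D (-1.66) and TpnC25D (-1.50). Cuticle genes were lower in 42 of 64 and higher in 3 (44 and 3 adjusted over the list alone; -1.45, adjusted p = 9.08e-16), and Osiris genes in 6 of 7 (7 adjusted over the list alone; -5.46, adjusted p = 0.000468), with the gap between the wild-type libraries given above. Nuclear oxidative phosphorylation genes were lower in 49 of 77 and higher in 2 (59 and 2 adjusted over the list alone; -0.83, adjusted p = 1.43e-11), as with UQCR-6.4 (-1.39) and ND-75 (146 ± 0.763 against 370 ± 28.5 CPM, -1.34). Mitochondrial ribosomal proteins were lower in 18 of 70 (21 adjusted over the list alone; -0.41, adjusted p = 3.09e-07), as with mRpL20 (-1.35) and mRpL55 (-1.27). All of them had adjusted p = 0.0518 to 0.593 with an estimated correlation.

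The 3 other calls each depended on single libraries. Cytosolic ribosomal proteins were tested as lower (median log2 fold change -0.30, adjusted p = 0.00011, adjusted p = 0.752 with an estimated correlation; 2 of 89 called, 0 adjusted over the list alone), but as higher without triple 1 (adjusted p = 0.995). Glue genes were higher in 6 of 11 (7 higher and 2 lower adjusted over the list alone; 2.75, adjusted p = 0.0189, adjusted p = 0.686 with an estimated correlation), a call lost without triple 2 (adjusted p = 0.116). P450 genes were higher in 16 of 71 and lower in 5 (19 and 6 adjusted over the list alone; 0.29, adjusted p = 0.0433, adjusted p = 0.552 with an estimated correlation). Their call was lost without wild type 2 (0.346), CTCF 1 or 2 (0.0571 and 0.0572), CTCF Su(Hw) 2 (0.069), CTCF Pita 1 (0.051) and triple 1 or 2 (0.0635 and 0.179). Turandot genes, which encode stress-induced humoral factors, had 3 tested members, too few for the list test, and each was higher: TotA (223 ± 60.9 against 76.5 ± 3.85 CPM, 1.55, adjusted p = 0.000216), TotC (2.89, or 3.64 without wild type 1) and TotE, with 89 reads against 0, at least 25.9-fold (fitted log2 fold change 8.45, or 7.86 without triple 1). Mip, a neuropeptide gene, rose by 2.08, the lipase gene Lip4 by 1.70, and GstD6 by 2.97, while Lsp1alpha fell by 1.60 and the collagen gene Col4a1 of basement membranes by 1.43. Library totals as scaling moved the median of all genes by 0.15 and turned no called list.

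Steps between mutants ask what a further mutation adds. With the Su(Hw) mutation added to the CTCF mutant, w rose (614 reads against 2, a ratio of 107, 95% interval 29.5 to 887), as did Hsp70Ab (788 against 2, a ratio of 138, 38.0 to 1140) and LManIV, a lysosomal mannosidase gene (187 against 0, at least 21.8-fold). Lower were Alp2, an alkaline phosphatase gene (0.189 ± 0.00433 against 27.5 ± 3.67 CPM, log2 fold change -7.07, SE 0.92, adjusted p = 0.000255), and the cuticle genes Acp65Aa (-4.81) and Lcp65Ae (-4.72). Mitochondrially encoded genes fell in 14 of 14 (14 adjusted over the list alone; median -2.76, adjusted p = 8.44e-08), with mt:ND2 (-4.42) and mt:ND3 (125 ± 8.4 against 1110 ± 314 CPM, -3.15) as examples, beside a mitochondrial share of 8.67% and 8.80% against 34.6% and 24.2%. Cytosolic ribosomal proteins fell in 81 of 89 (83 adjusted over the list alone; -1.49, adjusted p = 1.29e-25). Nuclear oxidative phosphorylation genes fell in 64 of 77, with 2 higher (64 and 6 adjusted over the list alone; -1.56, adjusted p = 9.4e-17), for example COX7C (-2.32) and ND-B12 (-2.28). Neuronal genes rose in 15 of 30 (17 adjusted over the list alone; 0.79, adjusted p = 0.000492), with brp at 3.89. Testis genes rose in 19 of 34 (20 adjusted over the list alone; 1.59, adjusted p = 1.43e-06) and heat shock genes in 12 of 15 (12 adjusted over the list alone; 2.48, adjusted p = 1.14e-06). Cuticle genes fell in 36 of 64 (38 adjusted over the list alone; -1.23, adjusted p = 4.39e-10). The 14 lists called here had adjusted p = 0.434 to 0.746 with an estimated correlation. The test called 4385 genes, 2121 higher and 2264 lower, and the larger side turned in 2 of 23 alternatives. Library totals turned it too (6815 and 379) and moved the median of all genes by 1.06. The count was 2631 and 2907 without CTCF 1 or 2, and 2577 and 2355 without CTCF Su(Hw) 1 or 2.

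With the Pita mutation added to the CTCF mutant, the larval cuticle gene Lcp65Ae fell (6.74 ± 2.04 against 247 ± 27.6 CPM, n = 2; log2 fold change -5.21, SE 0.48, adjusted p = 5.53e-05), as did the P450 gene Cyp6a2 (1.03 ± 0.0486 against 32.5 ± 1.57 CPM, -4.95) and Mdr50 (-3.38). Higher were CTCF itself (1.63, SE 0.24, adjusted p = 0.00045), the stress gene TotA (1.83) and the testis gene S-Lap7, a sperm aminopeptidase gene (3.43). Glutathione S-transferases fell in 19 of 31 (19 adjusted over the list alone; median -1.10, adjusted p = 3.44e-06), with GstD7 at -2.38, and P450 genes in 28 of 71, with 3 higher (the same adjusted over the list alone; -0.45, adjusted p = 0.000243; above 0 under library totals). UDP-glycosyltransferases fell in 15 of 30, with 1 higher (17 and 1 adjusted over the list alone; -0.73, adjusted p = 0.00546; above 0 under library totals). Library totals moved the median of all genes by 1.06. Digestive enzymes fell in 25 of 47, with 3 higher (-1.11, adjusted p = 0.00112), for example the protease gene Jon25Bii (-2.80). Muscle genes fell in 16 of 24 (-0.83, adjusted p = 2.11e-06; above 0 under library totals). Neuronal genes rose in 16 of 30 (0.76, adjusted p = 6.87e-06) and testis genes in 21 of 34 (2.02, adjusted p = 5.35e-09). Antimicrobial genes were higher in 10 of 35 and lower in 2 (adjusted p = 0.0171). Each of these 5 lists had the same counts adjusted over the list alone. The call of antimicrobial genes was lost without CTCF 2 (0.0517) and CTCF Pita 1 (0.0802). The 13 lists called here had adjusted p = 0.202 to 0.672 with an estimated correlation. The test called 4664 genes, 2268 higher and 2396 lower (2602 and 2191 with upper-quartile factors, 1 of 2 alternatives out of 23 that turned the larger side, and 6941 and 383 under library totals). Without CTCF 1 the count was 3024.

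With the Su(Hw) mutation added to the CTCF Pita mutant, Dso2, an immune-induced peptide gene, rose (238 reads against 0, at least 102-fold). Also higher were Jon44E, a gut protease gene (5448 ± 1640 against 707 ± 144 CPM, n = 2; log2 fold change 2.95, SE 0.37, adjusted p = 0.000734), the P450 genes Cyp6d2 (2.88), Cyp4e3 (2.27) and Cyp9b1 (1.94), and w (2.76, SE 0.23). Lower were Cralbp (0 reads against 118, at least 30.5-fold), the cuticle gene Ccp84Ab (-2.79), fne (-1.98), the limb gene Dll (-1.55) and br, an ecdysone-response transcription factor gene (-1.02). Antimicrobial genes rose in 26 of 35, with 1 lower (29 and 2 adjusted over the list alone; median 3.06, adjusted p = 1.49e-10). Digestive enzymes rose in 25 of 47, with 2 lower (32 and 2 adjusted over the list alone; 1.21, adjusted p = 2.61e-09), and P450 genes in 31 of 71, with 3 lower (37 and 4 adjusted over the list alone; 0.66, adjusted p = 9.12e-08). Neuronal genes fell in 11 of 30 (15 adjusted over the list alone; -0.64, adjusted p = 3.46e-06), as did testis genes in 14 of 34 (16 adjusted over the list alone; -0.73, adjusted p = 4.05e-05). Patterning genes fell in 6 of 18 (7 adjusted over the list alone; -0.80, adjusted p = 7.7e-05). Proliferation genes were lower in 6 of 24 (6 adjusted over the list alone; -0.34, adjusted p = 0.00322), but not called without triple 1 (adjusted p = 0.0696). The 17 lists called here had adjusted p = 0.194 to 0.575 with an estimated correlation. The test called 1773 genes, 1045 higher and 728 lower, a majority that turned with upper-quartile factors (848 and 928) and library totals (310 and 920). Library totals moved the median of all genes by -0.34. The count was 885 and 895 without CTCF Su(Hw) 1 or 2, 671 and 1053 without CTCF Pita 1 or 2, and 2808 and 639 without triple 1 or 2.

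Hox genes, which set segment identity, had 6 of 8 members with enough reads. In this step the list was called lower (median log2 fold change -0.59, adjusted p = 0.0444, adjusted p = 0.37 with an estimated correlation), with 2 of 6 called (3 adjusted over the list alone). The call was lost without CTCF Su(Hw) 1 or 2 (0.0515 each), CTCF Pita 1 or 2 (0.115 and 0.0543) and triple 1 or 2 (0.085 and 0.0823). Ubx stood at 5.89 ± 1.51 CPM in the triple mutant and 12.1 ± 0.673 in the CTCF Pita mutant (n = 2; -0.99, adjusted p = 0.018, lost without CTCF Pita 1 at 0.0753 and triple 2 at 0.0913). The abd-A gene stood at 19.6 ± 1.24 and 30.9 ± 0.48 CPM (-0.65, adjusted p = 0.0266). Its call was lost without CTCF Su(Hw) 1 or 2 (0.0642 and 0.0638), CTCF Pita 1 or 2 (0.0934 and 0.0735) and triple 2 (0.111). Against wild type edgeR called 0 of 6 Hox genes in each of the 4 mutants, with 1, 1, 2 and 1 at an unadjusted p under 0.05 in the CTCF, CTCF Su(Hw), CTCF Pita and triple mutants, and DESeq2 and limma-voom called 0 as well.

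With the Pita mutation added to the CTCF Su(Hw) mutant, Lip3 rose (342 ± 33.8 against 1.23 ± 0.0281 CPM, n = 2; log2 fold change 8.11, SE 0.34, adjusted p = 6.67e-07), as did Drs, which encodes the antifungal peptide drosomycin (219 ± 59.8 against 3.71 ± 0.647 CPM, 5.87). Also higher were the gut protease genes Jon44E (4.66) and thetaTry (3.76), the insulin-like peptide gene Ilp3 (3.02), AstA (1.99), TotA (2.25) and TotC (2.18). Lower were Mdr50 (-4.29, SE 0.34), Wnt2, which encodes a signaling ligand (1.65 ± 0.513 against 22.6 ± 2.92 CPM, -3.84), the acetylcholine receptor gene nAChRalpha7 (-3.71) and brp (9.79 ± 0.371 against 95.6 ± 7.19 CPM, -3.29, adjusted p = 3.4e-06). So were Hsp70Bb (-2.15) and the muscle genes Mhc, for myosin heavy chain (-1.69), Obsc and bt (-1.48 each). Cytosolic ribosomal proteins rose in 68 of 89 (76 adjusted over the list alone; median 0.79, adjusted p = 9.25e-19), for example RpS29 (1.31). Antimicrobial genes rose in 28 of 35, with 1 lower (31 and 1 adjusted over the list alone; 3.56, adjusted p = 1.1e-12). Neuropeptide genes rose in 7 of 22 (8 adjusted over the list alone; 0.76, adjusted p = 0.00571), a call lost without triple 1 (adjusted p = 0.142). Muscle genes fell in 8 of 24 (9 adjusted over the list alone; -0.47, adjusted p = 7.7e-05) and neuronal genes in 8 of 30 (8 adjusted over the list alone; -0.51, adjusted p = 0.00101). The 11 lists called here had adjusted p = 0.351 to 0.781 with an estimated correlation. The test called 2390 genes, 1284 higher and 1106 lower, but 511 and 1536 under library totals. These moved the median of all genes by -0.34. The count was 683 and 573 without CTCF Su(Hw) 1 or 2, and 1338 without triple 2.

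The interaction asks whether the effects of the Su(Hw) and Pita mutations on the CTCF background add up. Arc1, which encodes a capsid-forming synaptic protein (FBgn0033926; 2R, 14357927 to 14360297), stood at 1175 ± 155 CPM in the CTCF mutant, 225 ± 17.6 in the CTCF Su(Hw) mutant and 786 ± 92.7 in the CTCF Pita mutant, but at 5293 ± 429 in the triple mutant (n = 2 each; interaction 5.14 on the log2 scale, SE 0.29, adjusted p = 3.07e-06). CG15254 (FBgn0028949; 2L, 15613905 to 15614828) stood at 119 ± 11.4, 6.41 ± 0.147 and 40.4 ± 9.2 CPM in these groups and at 107 ± 17.8 in the triple mutant (5.61, SE 0.28). CG11300 (FBgn0034901; 2R, 23751915 to 23752495) fell from 623 ± 163 CPM in the CTCF mutant to 2.68 ± 0.138 and 11.5 ± 1.19 with either mutation, and stood at 13.9 ± 1.13 with both (8.12, SE 0.38, adjusted p = 1.35e-06). The additive level of CG11300 would be 0.709 reads over both triple libraries, so the size of this interaction rests on a level too low to measure. CG17224 (FBgn0031489; 2L, 3016441 to 3018308; 4.89) and CG1468 (FBgn0030157; X, 9878422 to 9879279; 4.63) completed the 5 smallest adjusted p. In all 4800 genes were called, 2458 higher and 2342 lower than additive, a split that turned with upper-quartile factors (2323 and 2484) and library totals (344 and 6457). Library totals moved the median of all genes by -1.40.

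The interaction subtracts both separate steps from the CTCF mutant, so a sign opposite to theirs is no separate result. Cytosolic ribosomal proteins lay above additive in 83 of 89 (85 above and 1 below adjusted over the list alone; median 2.04, adjusted p = 4.22e-24), for example RpL36 (3.07). Mitochondrial ribosomal proteins lay above in 59 of 70 (62 adjusted over the list alone; 1.31, adjusted p = 7.11e-15; below 0 under library totals). So did nuclear oxidative phosphorylation genes in 61 of 77, with 6 below (62 and 8 adjusted over the list alone; 1.79, adjusted p = 1.31e-12). Mitochondrially encoded genes lay above in 14 of 14 (14 adjusted over the list alone; 3.37, adjusted p = 1.47e-06), with the mitochondrial shares of reads given at the start. Digestive enzymes lay above in 27 of 47, with 2 below (2.19, adjusted p = 4.58e-06), such as Jon44E (6.00) and thetaTry (5.14). Cuticle genes lay above in 25 of 64, with 1 below (1.05, adjusted p = 3.84e-05; below 0 under library totals). Neuronal genes lay below in 21 of 30 (23 adjusted over the list alone; -1.20, adjusted p = 8.51e-07), such as brp (-3.74), and testis genes in 21 of 34 (-2.88, adjusted p = 6.08e-07). The digestive, cuticle and testis lists had the same counts adjusted over the list alone. The Ubx interaction (-1.25, SE 0.34, adjusted p = 0.0122) was lost without CTCF 2 (adjusted p = 0.0605). The 14 lists called here had adjusted p = 0.478 to 0.54 with an estimated correlation.

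Not called in any comparison were 8 lists, with camera adjusted p of 0.167 to 0.835 for insulator and architectural proteins (24 members), 0.409 to 0.791 for glial genes (9), 0.229 to 0.906 for germline genes (14), 0.277 to 0.853 for dosage compensation (7), 0.0964 to 0.835 for lipid metabolism (15), 0.167 to 0.869 for late ecdysone-response genes (6), 0.271 to 0.992 for ecdysone synthesis (7) and 0.0861 to 0.891 for histones (5). Single members of them moved, such as whd, ACC and FASN1 above. Of Y-linked genes kl-3, a dynein gene of sperm, was the 1 member tested. It stood at 2.05 above wild type on the log2 scale in the CTCF Pita mutant (SE 0.74, adjusted p = 0.0495), a call lost without wild type 1 or 2 (0.259 and 0.0858), CTCF 1 or 2 (0.0633 and 0.064), CTCF Su(Hw) 1 or 2 (0.0807 and 0.0825) and CTCF Pita 1 or 2 (0.195 and 0.0693). Median, mean and test differed in sign for some uncalled lists. These were neuronal, dosage compensation, late ecdysone and muscle genes in the CTCF mutant against wild type; insulator, fat body, ecdysone synthesis, digestive, glutathione S-transferase, UDP-glycosyltransferase and histone genes in the CTCF Su(Hw) mutant; glial, fat body, digestive and histone genes in the CTCF Pita mutant; and insulator, germline, lipid, late ecdysone and hemocyte genes in the triple mutant.

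The CTCF Su(Hw) and CTCF Pita mutants shared 2319 genes called in the same direction against wild type, 1067 higher and 1252 lower, and 43 in opposite directions. Independent draws, which do not allow for the shared wild-type libraries, would give 666. Over all genes the covariance of their log2 fold changes was 0.764, against 0.0577 in simulations that shared wild type with no gene changed. With no library in common, the CTCF Su(Hw) mutant against the CTCF mutant and the CTCF Pita mutant against wild type shared 2270 in the same direction and 130 in opposite ones, against 829 in the same direction for independent draws. The reverse choice of controls gave 2202 and 106, against 777. The triple mutant shared 1210 with the CTCF Su(Hw) mutant (73 opposite; covariance 0.665 against 0.0578 simulated) and 1483 with the CTCF Pita mutant (30 opposite; 0.747 against 0.0582). The CTCF mutant shared 137, 142 and 142 with the CTCF Su(Hw), CTCF Pita and triple mutants, with 55, 55 and 44 in opposite directions. Its covariance with the CTCF Su(Hw) and CTCF Pita mutants, 0.052 and 0.0272, was no higher than the 0.058 and 0.0574 that a shared wild type alone gave, and with the triple mutant it was 0.12 against 0.0583. Called against wild type in all 4 mutants and in the same direction were 68 genes, 32 higher and 36 lower, among them PGRP-SC1a. Independent draws would give 1.18 without allowing for the shared wild-type libraries. The 20 simulations that share them gave 0, but with no gene changed hardly any gene is called in these, so they do not show what sharing adds where many genes are called. The 3 combined genotypes shared 1024 of the 5664 genes called in any of them, 422 higher and 602 lower.

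Genes within 1 Mb of the CTCF, su(Hw) and pita genes were compared with the rest. Of 630 such genes, 12 were called in the CTCF mutant against wild type (1.9%, against 3.46% of 9952 others; odds ratio 0.542, two-sided Fisher's exact p = 0.0392, adjusted p = 0.313 over 8 comparisons). In the other 7 comparisons the adjusted p ran from 0.562 to 0.934. The 8 tested genes within 20 kb of su(Hw) had a median log2 fold change of 0.16 in the CTCF Su(Hw) mutant and -0.05 in the triple mutant against wild type, and the 8 within 20 kb of pita had -0.47 in the CTCF Pita mutant and -0.38 in the triple mutant. Single neighbours reached 0.974 and 1.11 near su(Hw), and near pita Dcp-1 was highest and called (log2 fold change 1.33, adjusted p = 0.00197, and 1.35, adjusted p = 0.00244).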

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

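The interaction was planned, while the tests of explanations in this part (scalings, neighbouring genes, Dcp-1, w level, glue score, shift by mitochondrial reads, principal component gap and reads of X-linked genes) were chosen only after the results were seen.

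The su(Hw) and pita genes stood above wild type in each genotype that carries their own mutation. Scaling is argued against, as the smallest log2 fold change over 4 scalings was 2.52, and so are neighbouring genes for su(Hw), where tested genes within 20 kb had medians of 0.16 at most (single highest 1.11), but not for pita, where Dcp-1, on the other strand inside it, was higher by 1.33 and 1.35, less than pita, so that sharing of reads cannot be told apart. For su(Hw), a candidate explanation, held as a hypothesis, is a construct that expresses Su(Hw) and carries a white marker gene, since w was 4.89 and 4.34 above wild type on the log2 scale in the same 2 genotypes (4.50 and 3.96 without wild type 1). For pita such a construct cannot be told apart from other origins: w in the CTCF Pita mutant was 1.58 higher at 2.97 ± 1.06 CPM, lost its call without wild type 1 (adjusted p = 0.0834) or CTCF Pita 1 (0.0578; 0.00238 to 0.268 over 23 alternatives), and stood at 19.7 CPM in the triple mutant against 28.9 in the CTCF Su(Hw) mutant. A biological explanation, in which the mutant proteins act on their own genes, was not tested, and how the alleles were made is not given in the sources used here.

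Between 2248 and 4664 genes were called when a genotype with a Su(Hw) or Pita mutation was compared with wild type or the CTCF mutant. Developmental age as scored by glue genes is argued against as the whole cause between the CTCF and CTCF Su(Hw) mutants. Their glue levels overlapped (7.3 and 6.2, 6.8 and 6.8 log2 CPM). The covariate could thus hardly change the calls between them (4385, 4588 with it). Against wild type it left 1645 of 4001 calls for the CTCF Pita mutant, so age may account for part there. Reads taken up by mitochondrial transcripts are argued against as the whole cause: their shares can shift all other genes by at most 0.0966 on the log2 scale against wild type and 0.481 against the CTCF mutant, and 100% and at least 58.2% of the called genes lay past the largest shift of their comparison by more than 2 SE, so that they may add to calls against the CTCF mutant. Handling the 3 combined genotypes apart from the rest cannot be told apart from genotype, as the gap of 38.7 on the first principal component follows both and the labels name no batch or date. The biological explanation, an effect of the Su(Hw) and Pita mutations, stays open beside it, as do strain background and age not scored by glue genes, which were not tested.

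CG3588 and CG14419 had 1 read and 0 reads in the CTCF Su(Hw) mutant and 0 each in the triple mutant, against 2672 and 379 in wild type. Loss of the X chromosome stretch between w and CG3603 is argued against, because its other 14 genes had 39 reads over the 4 libraries with the Su(Hw) mutation (27 and 12, against 65 in wild type, 52 of them in wild type 1 and 13 in wild type 2). The biological explanation, an effect of the Su(Hw) mutation, stays open, as the loss of CG3588 followed this mutation from the CTCF mutant (274 reads to 1) and from the CTCF Pita mutant (2517 to 0), but so would a difference of the strains that carry it. Both genes were also lower in the CTCF mutant against wild type (log2 fold change -2.52, adjusted p = 0.000233, and 0.000235 to 0.0113 over the 10 fits without 1 library, and -3.04, adjusted p = 0.00193), but CG3588 was at -0.67 in the CTCF Pita mutant (adjusted p = 0.0211, lost without wild type 2 at 0.114 and CTCF Pita 1 at 0.118) and CG14419 at -0.25 (0.419). A shorter missing segment, from w to CG3588, cannot be told apart from lower transcription: its other genes had 2 reads over these 4 libraries, but 11 in wild type, 39 in the CTCF Pita mutant and 0 in the CTCF mutant, and its end was chosen from the reads.

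A difference between groups was found where the interaction of the Su(Hw) and Pita mutations passed its test, for 4800 genes in all. The named genes were CG11300 (8.12, where the additive level is 0.709 reads in the triple mutant and the size cannot be measured), CG15254 (5.61), Arc1 (5.14), CG17224 (4.89), CG1468 (4.63) and w (-3.90, with 0.271 ± 0.0259 CPM in the CTCF mutant). Further named genes lost the call without single libraries: Ubx (-1.25) without CTCF 2 (adjusted p = 0.0605; 0.00561 to 0.0605 over 23 alternatives), abd-A (-0.83) without CTCF 1 or 2 (0.0643 and 0.0519) and CTCF Su(Hw) 1 or 2 (0.0511 and 0.074; 0.00603 to 0.074), and Cp190 (-1.73) without CTCF 1 or 2 (0.0619 and 0.0734) and CTCF Su(Hw) 1 or 2 (0.0506 and 0.0551; 4.28e-05 to 0.0734; log2 value -2.78 without triple 1). Antp (-0.91) lost it without CTCF 2 (0.155), CTCF Su(Hw) 2 (0.153), CTCF Pita 1 or 2 (0.0889 and 0.0548) and triple 1 or 2 (0.0578 and 0.0876; 0.0207 to 0.155).

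Called lists (median) were cytosolic (2.04) and mitochondrial ribosomal proteins (1.31), nuclear oxidative phosphorylation (1.79) and mitochondrially encoded genes (3.37). Others were digestive (2.19), cuticle (1.05), neuronal (-1.20) and testis genes (-2.88). P450 genes (0.67; 27 of 71 above and 4 below), glutathione S-transferases (0.97; 17 of 31 and 1) and UDP-glycosyltransferases (0.83; 12 of 30 and 1) had the same counts adjusted over the list alone. Under library totals the medians of these 3 lists, of cuticle genes and of mitochondrial ribosomal proteins turned negative. Antimicrobial genes (1.66; 4 of 35 above and 1 below, 1 and 0 adjusted over the list alone) lost the call without triple 2 (adjusted p = 0.076; 0.000323 to 0.54 over 14 alternatives). Early ecdysone-response genes (-0.93; 9 of 17 below and 2 above, 10 and 2 adjusted over the list alone) lost it without CTCF 2 (0.055; 0.002 to 0.54). Heat shock genes (-1.52; 2 of 15 below, 2 adjusted over the list alone) lost it without CTCF 2 (0.0593), CTCF Pita 1 (0.242) and triple 1 (0.191; 0.000211 to 0.54). None of the 14 lists was called with an estimated correlation.

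Reads that were not assigned to a gene lay above the higher wild-type library in both libraries of some mutants. Unmapped reads were at least 6.65% in the triple mutant (wild type at most 6.48%), and reads mapped to several places at least 63.3% in the CTCF mutant (56.4%). Reads outside genes were at least 0.848%, 0.872% and 0.664% in the CTCF Su(Hw), CTCF Pita and triple mutants (0.646%). Reads in more than 1 gene were at least 4.27% in the CTCF mutant, 4.03% in the CTCF Su(Hw) mutant and 4.01% in each of the CTCF Pita and triple mutants (3.81%). With 2 libraries per group, no library was tested for lying far from the others of its group.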

How the results depend on the processing

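Of the alternatives below, summing the CTCF Su(Hw) libraries, leaving out wild type 1, CTCF Pita 1 and triple 2 together, removing mitochondrially encoded genes and the glue score were added after seeing the data. Those 3 libraries were picked by no rule. Where 1 library is left in a group, it is assumed to vary like the other groups, and where no cause is given, the cause was not tested. RLE and upper-quartile factors, the CPM filter, DESeq2, limma-voom and replicate number as a block each kept all 9 counts of called genes within 1.5 times (with the block 248 to 4592), though replicate numbers do not pair the libraries (correlations of -0.149 to 0.153). Removal of mitochondrially encoded genes gave counts 0.95 to 1.01 times as large, but under trimmed scaling it could hardly change them. No filter gave 733 genes in the CTCF mutant against wild type. Models of only the groups compared gave 536 there, 1277 in the triple mutant against wild type and 463 in the triple against the CTCF Pita mutant. A change of at least 2-fold, which by construction keeps fewer genes, left 1570, 2024 and 1227 in the CTCF Su(Hw), CTCF Pita and triple mutants against wild type. It left 2354 and 2693 in the CTCF Su(Hw) and CTCF Pita mutants against the CTCF mutant, and 790 and 1071 in the triple against the CTCF Pita and CTCF Su(Hw) mutants. The CTCF Su(Hw) libraries differ least from each other and may come from 1 RNA sample, and with them summed, which leaves fewer samples, the counts were 143 for the CTCF mutant and 1382 for the CTCF Su(Hw) mutant against wild type. The same fit gave 2584 for the CTCF Su(Hw) against the CTCF mutant, and 891 and 678 for the triple against the CTCF Pita and CTCF Su(Hw) mutants. Without the 3 libraries, the CTCF mutant against wild type gave 1328. With the glue score the 4 mutants against wild type gave 53, 2232, 1645 and 873. Leaving out 1 library at a time gave 67 to 835, 1142 to 4107, 1956 to 4563 and 1305 to 2307 for the CTCF, CTCF Su(Hw), CTCF Pita and triple mutants against wild type. It gave 2355 to 4870 and 3024 to 5113 for the steps from the CTCF mutant with Su(Hw) and Pita, 639 to 2808 and 573 to 3063 for the triple against the CTCF Pita and CTCF Su(Hw) mutants, and 3346 to 5186 for the interaction.

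Called lists (119 of 279 tests) numbered 0 with an estimated correlation, 102 with fry, 122 with the block, 124 without the 3 libraries and 110 to 125 without 1 library. The genes shared by all 4 mutants against wild type (68) numbered 65 with DESeq2, 36 at 2-fold and 183 without the 3 libraries. Genes near the mutated loci kept their side of the threshold in windows of 0.5 and 2 Mb.

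Named genes turned sign 11 times over all alternatives. With the glue score these were sro in the CTCF Su(Hw) and CTCF Pita mutants (-0.091 and -0.55), Eig71Ee in the CTCF Pita mutant (-0.57), and Sgs8 and Sgs7 in the triple mutant (-0.59 and -0.46), each against wild type. Without 1 library, in the CTCF Pita mutant against wild type, Osi7 ran from -4.40 to 0.40 (turned without wild type 1) and Dso2 from -7.06 to 0 (reached without wild type 2). Amy-d ran from -0.43 to 3.56 and Amy-p from -0.53 to 3.23 (turned without CTCF Pita 2). Hsp23 in the CTCF Pita mutant against the CTCF mutant ran from -0.17 to 2.70 (turned without CTCF Pita 1) and was at -0.16 without the 3 libraries. Lists turned 3 times by the same rule. The adjusted p of cytosolic ribosomal proteins in the triple mutant against wild type ran from 6.29e-16 to 0.995 (turned to higher without triple 1). That of nuclear oxidative phosphorylation genes in the triple against the CTCF Su(Hw) mutant ran from 3.16e-08 to 0.21 (turned to lower without triple 2) and was 0.234 without the 3 libraries. Over all alternatives, results for named genes kept direction and side of the threshold 20249 times, lost a call 2759 times and gained one 41 times. For lists this was 3560, 249 and 94. With 2 libraries per group, simulations over the 9 comparisons recovered 69.7% to 95.5% of 4-fold changes. For 2-fold changes this was 10.4% to 48.4%, and for 1.5-fold changes 0% to 10.4%. Small changes are mostly missed.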

Other observations

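The comparisons and lists in this part were planned, but what is given of them was picked with the results at hand, and ranges over alternatives include the settings added after seeing the data.

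Some gene groups moved in steps between mutants that are not described above. Hemocyte genes rose with the Su(Hw) mutation on the CTCF Pita background in 6 of 17 (8 adjusted over the list alone; median log2 fold change 0.46, adjusted p = 0.000984, adjusted p = 0.194 with an estimated correlation), among them PPO1 (102 ± 9.9 against 45.7 ± 6.93 CPM, n = 2; 1.16). On the CTCF background the same mutation gave 10 of 17 higher and 2 lower (the same adjusted over the list alone; 0.71, adjusted p = 0.0335, adjusted p = 0.434 with an estimated correlation), a list call lost without CTCF 1 or 2 (0.0514 and 0.0607; 0.00249 to 0.434 over 14 alternatives). There the scavenger receptor gene Sr-CI rose (29.1 ± 0.596 against 6.56 ± 1.09 CPM, 2.14) and NimC1 fell (-1.46). With the Pita mutation on the CTCF Su(Hw) background NimC1 rose (24.9 ± 3.65 against 6.45 ± 0.718 CPM, 1.94) and Col4a1 fell (365 ± 24 against 1131 ± 88.3 CPM, -1.63). Early ecdysone-response genes fell with the Su(Hw) mutation on the CTCF Pita background in 8 of 17 (11 adjusted over the list alone; -0.58, adjusted p = 0.000204, adjusted p = 0.253 with an estimated correlation; 9.4e-06 to 0.253 over 14 alternatives). CTCF Pita 1 and 2 stood at 5.21 and 4.59 log2 CPM in this list, and triple 1 and 2 at 4.22 and 4.01. The list call was kept without each single library, but Eip93F (-3.03, adjusted p = 0.019) went to -1.08 without CTCF Pita 1 (0.113) and lost its call without triple 1 or 2 too (0.0721 and 0.0963; 8.46e-06 to 0.114 over 23 alternatives). The nuclear receptor gene ftz-f1 stood at 9.32 ± 0.318 CPM in the CTCF mutant, 18.3 ± 0.179 in the CTCF Su(Hw) mutant (0.97) and 7.96 ± 1.31 in the triple mutant (-1.18 from the CTCF Su(Hw) mutant). Heat shock genes rose in the triple against the CTCF Pita mutant in 9 of 15 (12 higher and 1 lower adjusted over the list alone; 2.19, adjusted p = 7.54e-06, adjusted p = 0.334 with an estimated correlation). They fell in the triple against the CTCF Su(Hw) mutant in 5 of 15 (5 adjusted over the list alone; -0.57, adjusted p = 0.00509, adjusted p = 0.533 with an estimated correlation), a call lost without triple 1 (0.143; 7.23e-06 to 0.533). The lipase gene mag rose with the Su(Hw) mutation on the CTCF Pita background (689 ± 94.4 against 144 ± 15.6 CPM, 2.26), as did Apoltp, a lipid carrier gene of the fat body (296 ± 1.49 against 130 ± 9.46 CPM, 1.19).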
